A study of Mus musculus with 14 samples.

How the data were processed

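The study used NG Capture-C, in which chromatin of fixed cells is cut with DpnII, ligated within the fixed complexes and enriched with oligonucleotides for chosen promoter fragments, so that the fragments ligated to each promoter can be counted. Per the labels' protocols, cells were fixed with 2% formaldehyde for 10 min. Erythroid cells came from the spleens of mice given 3 doses of phenylhydrazine 12 h apart and killed on day 5, a treatment that destroys red cells and fills the spleen with erythroid precursors. E14 mouse embryonic stem (ES) cells were grown in culture with serum and LIF.

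The authors deposited whole-number counts per DpnII fragment and library, in a separate table for each captured promoter, called a viewpoint here. Per the submitters' processing notes, Trim Galore, Bowtie and the genome build mm9 were used; versions, settings and the counting tool are not given in the sources used here. The tables did not hold scaled values, because the column totals were whole numbers that differed between libraries. Each panel table lacked fragments around the captured promoters. Over 32 such empty promoter zones and 37 panel tables, 0 of 1184 pairs of zone and table held a fragment. The panel tables thus carry no counts at any captured promoter itself, and the other tables were not checked for this. The position of a viewpoint was taken as the centre of its own empty zone, a gap of at least 1300 bp with the most counts in the 3000 bp on each side.

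Libraries were matched to groups by the strain and capture marks in the column names. The panel experiment had 4 erythroid libraries, called C1 and C2 for the C57Bl6 strain and F1 and F2 for the C57Bl6 and CBA cross, and 3 ES libraries, called E0, E1 and E2. The panel columns show the group and strain but not which of the sample numbers in the labels they are. Further experiments gave 1 single capture library and 2 double capture libraries of alpha-globin from the cross, and 2 double capture libraries of C57Bl6 cells selected for the red cell surface marker ter119. In total 14 samples and 46 tables were listed. A further 34 columns were not used: 28 matched no sample and 6 repeated the ter119 libraries. In 5 tables no column was used, and the 2 samples of the cell number experiment were not analysed here. The labels do not say whether libraries of a group came from separate animals or cultures, so p-values measure the spread between these libraries. Before averaging, counts of library pairs were compared by chi-square over bins with at least 20 counts in a pair. The chi-square per degree of freedom was lowest for E1 and E2, at 1.28, which was still beyond sampling noise, and all libraries were counted separately.

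Counts were summed in 5 kb bins on the chromosome of the viewpoint (mm9, 1-based). Bins with a centre 5 to 500 kb from the viewpoint and a mean of at least 10 counts over the 7 libraries were tested. All 33 viewpoints were fitted together with edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3), with the log of the total count of each viewpoint and library as the offset, and Benjamini-Hochberg adjustment over all bins at a false discovery rate of 0.05. The combined alpha-globin and combined beta-globin tables stood for their pairs of near-identical genes, whose counts cannot be assigned to single copies. Normalised counts are counts per 100000 counts of the viewpoint in that library. Shares of counts on the viewpoint's chromosome, shares by distance class up to 1 Mb and counts in 7 regulatory windows were compared by two-sided exact permutation tests over the 35 splits of 4 against 3 libraries, whose smallest p is 0.0286, with Benjamini-Hochberg adjustment. Gene lists of viewpoints were compared by a two-sided permutation test with 100000 resamples. Single captures were given Wilson intervals at 95%, which cover counting error only, as does the floor of 3 counts for a value of 0.

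The groups, tests, windows, gene lists and the rule for named bins were fixed before the data were examined. The rule took bins past the threshold with a mean of at least 10 normalised counts, no overlap between erythroid and ES libraries and a distance of at least 10 kb. From these it took the bin with the largest fold change of each viewpoint and direction, kept the 12 viewpoints with the largest in each direction, and added the 3 largest bins per direction for alpha-globin, beta-globin and Slc25a37, all 7 windows, and the viewpoints with the most and fewest calls. Bins are named by viewpoint and start, as in HbbCombined_111010001. No gene annotation of mm9 was used here, so genes in or near a bin are not named.

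The bin test was tested on simulated data for the erythroid against ES comparison, with the real means and totals of 4749 bins, a dispersion of 0.03 and 200 changed bins. It recovered 14 of 67 bins changed 1.5-fold (20.9%), 43 of 67 changed 2-fold (64.2%) and 66 of 66 changed 4-fold. Of 128 calls, 5 were unchanged bins. Changes went up or down at random without a general shift, so these shares describe the simulation alone. Alternatives were TMM factors per viewpoint, the total on the viewpoint's chromosome, DESeq2 1.42.0, limma 3.58.1 on log2 values with a pseudocount of 1 or 5, bins of 2 or 10 kb, single fragments, other count filters and distances, single-promoter globin tables, each strain alone and each library left out. Values outside the model were computed with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.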

Results

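Contacts of gene promoters were counted by NG Capture-C in mouse erythroid cells and ES cells. The panel experiment held 33 viewpoints in 4 erythroid and 3 ES libraries. Its promoters belong to globin genes, genes of haem and iron metabolism, blood transcription factors, membrane proteins and receptors, pluripotency factors and other genes. Summed over the viewpoints, the erythroid libraries C1, C2, F1 and F2 held 1572834, 802390, 1015593 and 646922 counts, and the ES libraries E0, E1 and E2 held 1067834, 869768 and 969343. A single viewpoint held between 7829 and 111357 counts in a library. Erythroid and ES cells also differed in mouse strain and in coming from a spleen or from culture, so a difference between the groups is one between these sets of libraries.

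The first question was whether promoters contact known distal elements differently in the 2 cell types, at 7 windows chosen from textbook knowledge. The alpha-globin promoters had 14096 ± 1729 normalised counts (SD, n = 4) in erythroid libraries in the region upstream of the gene cluster that holds its erythroid enhancers (chromosome 11, 32140000 to 32175000, mm9), against 7683 ± 535 (n = 3) in ES libraries, a 1.83-fold rise. The beta-globin promoters had 9442 ± 1192 in the locus control region, the enhancer cluster of the beta-globin genes (chromosome 7, 111005000 to 111040000), against 3042 ± 470, a 3.10-fold rise. The pluripotency genes went the other way. The Sox2 promoter had 404 ± 78.4 normalised counts in its downstream control region (chromosome 3, 34648441 to 34668441) in erythroid libraries and 4076 ± 533 in ES libraries, 10.1-fold more in ES cells.

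The downstream window of Klf4 (chromosome 4, 55475225 to 55495225) held 747 ± 104 normalised counts in erythroid and 2524 ± 287 in ES libraries, 3.38-fold more in ES cells. The upstream window of Nanog (chromosome 6, 122607396 to 122617396) held 751 ± 69.1 and 2164 ± 10.1, 2.88-fold more in ES cells. The distant Myc window, known for enhancers of blood progenitors (chromosome 15, 63417925 to 63617925), held 1456 ± 56.9 and 3187 ± 443, 2.19-fold more in ES cells. Tal1, a blood transcription factor, had 2601 ± 563 normalised counts in its downstream window (chromosome 4, 114765873 to 114775873) in erythroid and 1843 ± 416 in ES libraries, and the groups overlapped (exact permutation p = 0.114). In each of the other 6 windows all 4 erythroid libraries lay on the same side of all 3 ES libraries, which gave an exact permutation p of 0.0286, the smallest 4 against 3 libraries allow, and 0.0333 adjusted over the list alone. The viewpoints as a whole had median log2 fold changes of -1.28 at Sox2, -1.02 at Klf4, -0.50 at Nanog and -0.83 at Myc. Their windows had -3.34, -1.76, -1.53 and -1.13. At alpha-globin, beta-globin and the first Tal1 viewpoint the medians were -1.95, -2.24 and -2.21, against 0.88, 1.63 and 0.50 in the windows. These medians cover bins up to 500 kb from the promoters, and the Myc window lies farther out. The 6 windows without overlap also passed when scaled by the counts on the viewpoint's chromosome. With windows widened by 5 kb on each side, the alpha-globin difference fell from 0.88 to 0.57 on the log2 scale and no longer passed (exact permutation, adjusted p = 0.0667, against 0.0333 with the other scaling).

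**Figure D1:**
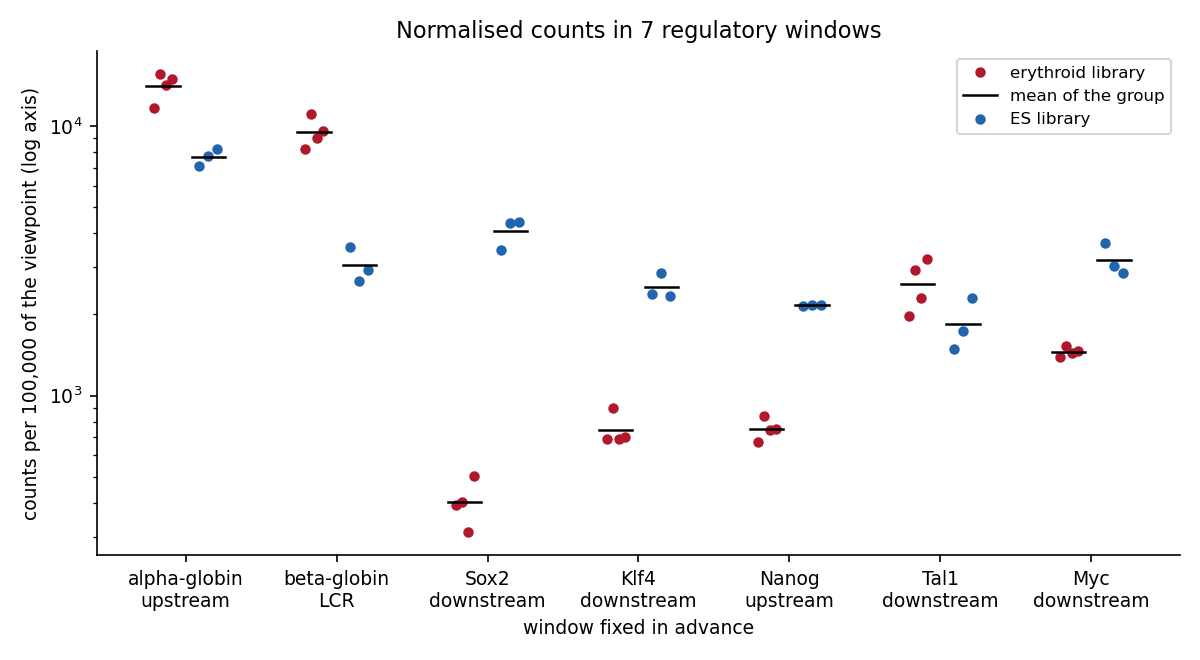
Normalised counts (counts per 100000 of the viewpoint, log axis) in 7 regulatory windows fixed in advance, with a point for each erythroid library (4, red) and ES library (3, blue) and a line at the mean of each group. Erythroid libraries lie above ES libraries at alpha-globin and beta-globin and below them at Sox2, Klf4, Nanog and Myc, and the groups overlap at Tal1.

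**Figure D2:**
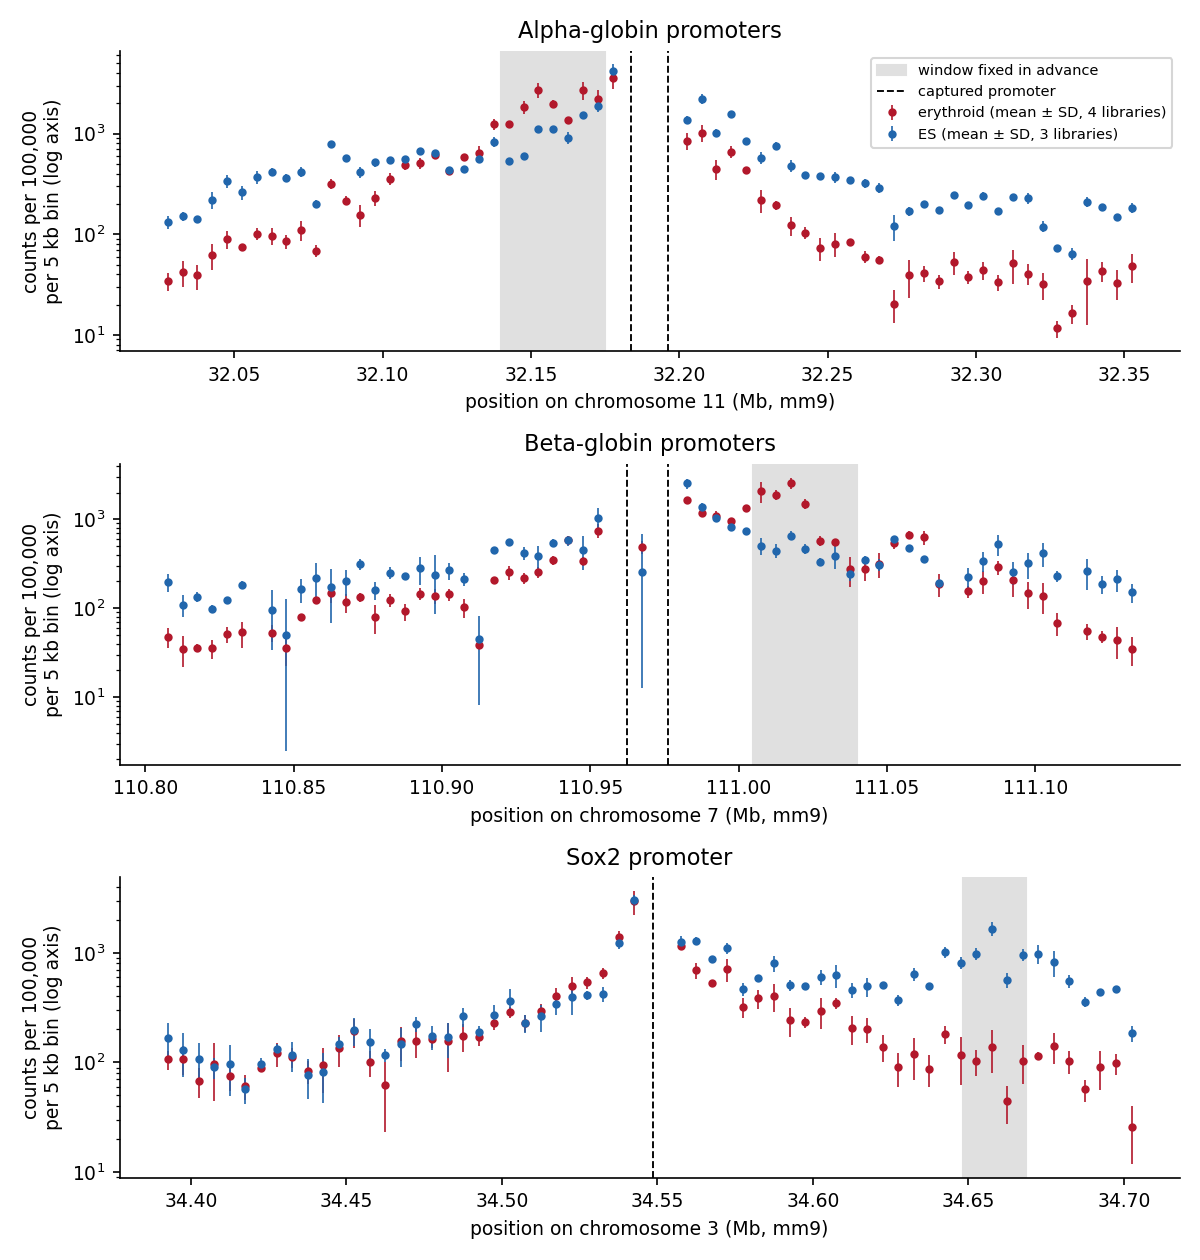
Normalised counts per 5 kb bin (log axis) against position in mm9 around the alpha-globin, beta-globin and Sox2 promoters, as mean ± SD of 4 erythroid (red) and 3 ES (blue) libraries; grey marks the regulatory window and dashed lines the captured promoters. Mean erythroid values exceed ES values in the bins inside both globin windows, and at Sox2 they lie below ES values inside the window.

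The next question was which parts of the 500 kb on either side of each promoter differed between the cell types. Relative to the total of each viewpoint, most bins held fewer counts in erythroid cells, and a small set of bins, among them bins in the globin enhancer regions, held more. Of 4749 bins tested, 284 were higher and 2937 lower in erythroid libraries by edgeR's quasi-likelihood test. The bins as a whole were shifted, with a median log2 fold change of -0.81. Scaled by TMM factors per viewpoint, which set this shift near 0 (median -0.07), 1090 bins were higher and 1081 lower. TMM factors raised the bins of each viewpoint together, so the 284 higher bins stayed higher by construction, and 1081 of the 2937 lower bins remained lower while 141 turned higher. Scaled by counts within 1 Mb of the promoter, a choice made after the data were seen, 831 were higher and 1601 lower (median -0.22). A call of a lower bin therefore holds against the total of its viewpoint, and only for the 1081 also against the other bins of the viewpoint.

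Scaled by the viewpoint total, the alpha-globin viewpoint had the most calls, at 177 of 198 bins, and the viewpoint of Epb4.9, which encodes the membrane skeleton protein dematin, had the fewest, at 30 of 84. With TMM factors the most were at Lmo2-1, with 59 higher and 77 lower of 187 bins. The fewest were at Nfe2, with 17 and 9 of 74. These counts depend on the number of bins tested, and as shares neither was the extreme. The second Tal1 viewpoint had 25 and 28 of 67, and the first Myc viewpoint 19 and 11 of 161. The 20 higher bins of alpha-globin had a median distance of 414 kb from its promoters. Shifts differed between viewpoints. The median log2 fold change was -2.24 for beta-globin, -2.21 for Tal1-1, the first Tal1 viewpoint, -1.95 for alpha-globin, -1.91 for Pdzk1ip1, a neighbour of Tal1, and -1.64 for Slc25a37, which encodes the mitochondrial iron importer mitoferrin. It was -0.05 for Klf1, an erythroid transcription factor, and -0.09 for Epb4.9. The second Tal1 viewpoint, which shares the promoter zone of Tal1-1, had -1.33, but over 67 tested bins against 109, so these medians are not of the same bins. Bins 5 to 20 kb, 20 to 100 kb and 100 to 500 kb away had medians of -0.38, -0.50 and -0.97.

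**Figure D3:**
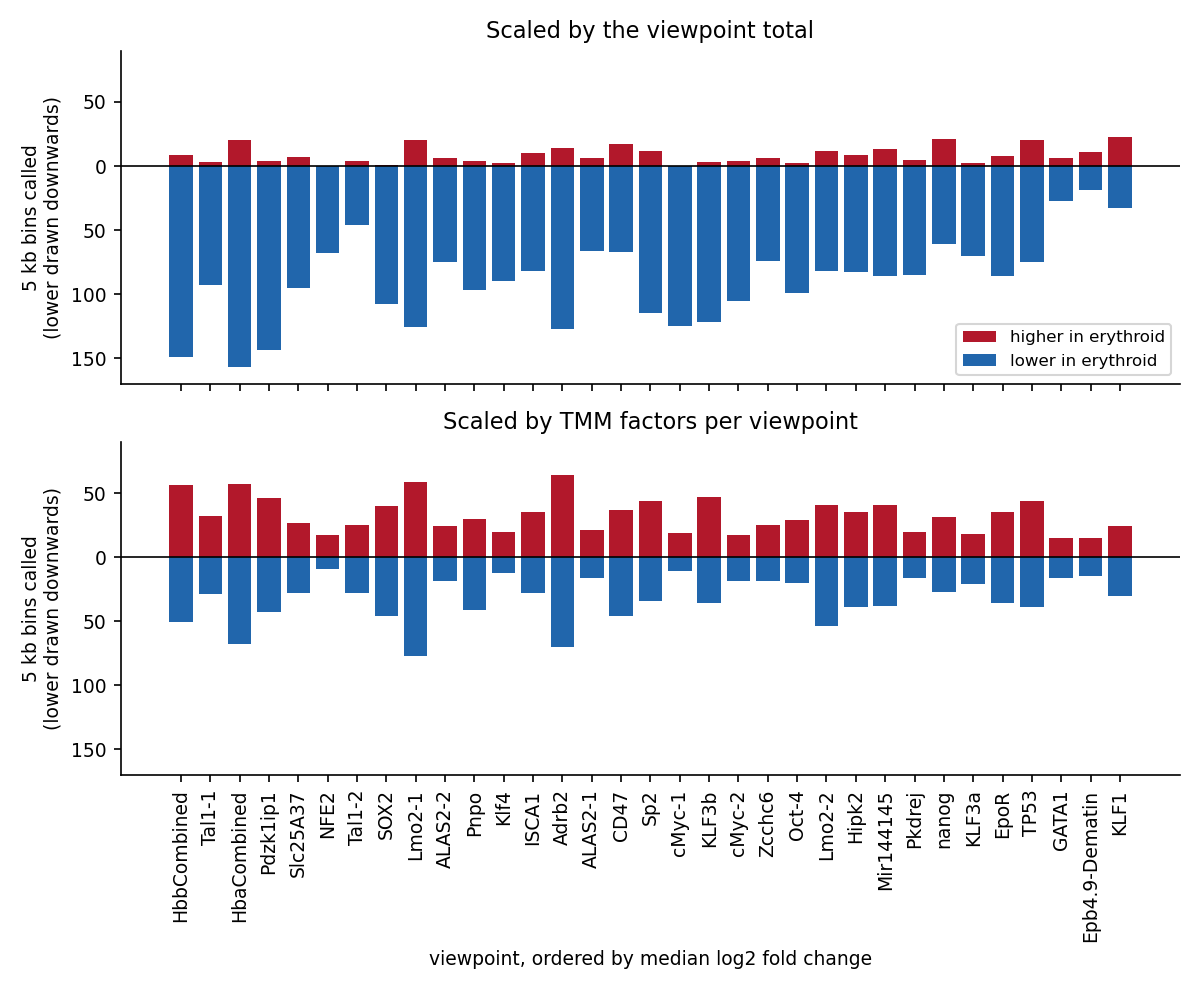
Number of 5 kb bins past the threshold of edgeR's test in each of 33 viewpoints, higher in erythroid cells drawn upwards (red) and lower drawn downwards (blue), ordered by median log2 fold change; the upper panel is scaled by the viewpoint total and the lower by TMM factors. The totals are 284 higher and 2937 lower in the upper panel and 1090 higher and 1081 lower in the lower panel.

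The bins with the largest rise in erythroid cells included the enhancer regions of both globin loci. At beta-globin the 3 largest rises were adjoining bins of the locus control region, and HbbCombined_111010001 had 1897 ± 231 normalised counts in erythroid and 442 ± 79.3 in ES libraries (log2 fold change 2.09 ± 0.18 SE, edgeR adjusted p = 4.86e-11). At alpha-globin the bins at 32145001 and 32150001 on chromosome 11, both in the upstream enhancer region, rose by log2 fold changes of 1.61 and 1.30, and a bin 446 kb away at 31735001 rose by 1.63. At Slc25a37 the bins at 69940001, 69935001 and 69920001 on chromosome 14 rose by 1.74, 1.64 and 1.31, the first from 739 ± 149 to 2483 ± 485 normalised counts. Cd47, a surface protein that protects red cells from phagocytosis, had 1531 ± 267 normalised counts in a bin at 49770001 on chromosome 16 in erythroid and 374 ± 56.2 in ES libraries (log2 fold change 2.02, edgeR adjusted p = 1.14e-10).

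Among blood transcription factors, Klf1 showed the largest log2 fold change, 3.09 ± 0.50 (SE), in a sparsely counted bin 492 kb away (8:87915001), with 49.7 ± 11.8 normalised counts in erythroid and 5.39 ± 2.01 in ES libraries. Both Lmo2 viewpoints, of a blood transcription factor partner, picked the same bin at 103960001 on chromosome 2, with log2 fold changes of 1.55 and 1.36. Gata1 rose by 1.49 at 7415001 and Alas2, the erythroid enzyme that starts haem synthesis, by 1.48 at 146900001, both on the X chromosome. Epb4.9 rose by 1.54 at 71105001 on chromosome 14. Pnpo, an enzyme of vitamin B6 metabolism, rose by 2.32 at 97300001 on chromosome 11, and Nanog by 1.79 at 122885001 on chromosome 6, 230 kb from its promoter. With TMM factors, which raise these values by construction, the log2 fold changes of these rises ran from 1.61 at Epb4.9 to 4.07 at HbbCombined_111010001.

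The named bins with the largest falls in erythroid cells all lay over 100 kb from their promoters. Tal1-1 fell by 4.42 on the log2 scale (± 0.29 SE, edgeR adjusted p = 1.48e-13) in a bin at 114515001 on chromosome 4, from 534 ± 184 normalised counts in ES to 22.7 ± 11.2 in erythroid libraries, and the second Tal1 viewpoint fell by 3.83 at 114920001. Its neighbour Pdzk1ip1 fell by 3.72 at 115030001 on the same chromosome. Among globin and iron genes, beta-globin fell by 4.07 at 110480001 on chromosome 7, Slc25a37 by 4.11 at 69645001 on chromosome 14 and the alpha-globin bin at 32460001 on chromosome 11 had a log2 fold change of -3.96. The next 2 bins of these viewpoints had log2 fold changes of -4.03 and -3.97 at beta-globin, -3.26 and -3.20 at Slc25a37 and -3.50 and -3.34 at alpha-globin. Without library F2 the -3.50 at alpha-globin became -4.13, and without C1 the -3.20 at Slc25a37 became -3.98.

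The bin with the largest fall at Sox2, SOX2_34660001, lay inside its downstream control region and fell by 3.75, from 566 ± 84.0 to 44.5 ± 16.8 normalised counts. Zcchc6, an RNA uridylyltransferase, fell by 3.91 at 60265001 on chromosome 13, and Cd47 had a log2 fold change of -3.39 at 50150001 on chromosome 16. The microRNA locus Mir144 fell by 3.36 at 77700001 on chromosome 11, the transcription factor gene Sp2 by 3.11 at 96570001 on the same chromosome and Adrb2, the beta-adrenergic receptor, by 3.04 at 61930001 on chromosome 18. The Zcchc6 bin was sparsely counted, with a mean of 10.1 counts, and its log2 fold change ran from -5.32 with the C57Bl6 libraries alone to -3.18 with the crossed ones alone, and was -4.82 without library F1. That of the Adrb2 bin was -3.66 without C1. With TMM factors all of these bins stayed lower, with smaller log2 fold changes, such as -2.53 at Tal1-1, -2.07 at beta-globin and -2.55 at Sox2.

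By gene list, the 2 globin viewpoints had 29 higher and 306 lower bins of 379, and 113 higher and 119 lower with TMM factors. The 4 haem and iron viewpoints (Alas2, Slc25a37 and Isca1, an iron-sulphur cluster protein) had 29 and 318 of 441, or 107 and 91 with TMM. The 9 viewpoints of blood transcription factors had 73 and 667 of 1127, or 278 and 300 with TMM, from Nfe2 with 0 higher and 68 lower of 74 bins (17 and 9 with TMM) to Klf1 with 23 and 33 of 126. The 3 membrane and receptor viewpoints had 36 and 172 of 401, or 87 and 97 with TMM. The 4 pluripotency viewpoints had 26 and 358 of 588, or 120 and 105 with TMM, of which Nanog gave 21 of the higher and Sox2 1.

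Whether erythroid genes as a list differed from other genes was tested on the net share of bins called, higher minus lower over tested. The erythroid list held the globin genes and blood transcription factors, Alas2, Slc25a37, Epb4.9, EpoR and Mir144, and left Isca1 and Cd47 among the other genes. The 13 erythroid genes averaged -0.526 ± 0.265 and the 15 other genes -0.561 ± 0.159 (SD over genes). The difference was 0.0354 (permutation p = 0.667). The difference of mean log2 fold change had the opposite sign, -0.0615 (permutation p = 0.750).

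The share of counts on the viewpoint's own chromosome was lower in erythroid cells for most genes. The median over viewpoints was 69.5% ± 3.12 (SD, n = 4) in erythroid and 82.4% ± 4.49 (n = 3) in ES libraries (exact permutation p = 0.0286). The largest differences were at beta-globin, with 65.2% ± 2.61 against 84.8% ± 3.57, and at Alas2-2, Tal1-1 and Lmo2-1. Oct-4, a pluripotency factor, had 75.7% ± 2.01 and 76.2% ± 4.33. Nanog had 74.9% ± 3.74 in erythroid and 65.7% ± 1.85 in ES libraries, without overlap, but the difference did not pass after adjustment (exact permutation, adjusted p = 0.0725).

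In all, 24 of 33 viewpoints were lower in erythroid cells (exact permutation, adjusted p = 0.0393), 0 were higher, also at an unadjusted p under 0.05, and 9 did not pass. The groups did not overlap in 26 viewpoints, 25 lower and 1 higher, against a chance share of 5.71% for a single viewpoint; the viewpoints come from the same 7 libraries and are not independent. Library E0 stood apart from the other ES libraries, with a median share of 77.2% against 84.6% and 85.3%. Counted as shares of fragments rather than of counts, 17 viewpoints reached the smallest p, 19 were needed to pass, and none passed (smallest adjusted exact p = 0.0555). Of these shares 17 were lower and 3 higher without overlap, and the median difference was -10.5 percentage points, against -12.0 for counts.

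**Figure D4:**
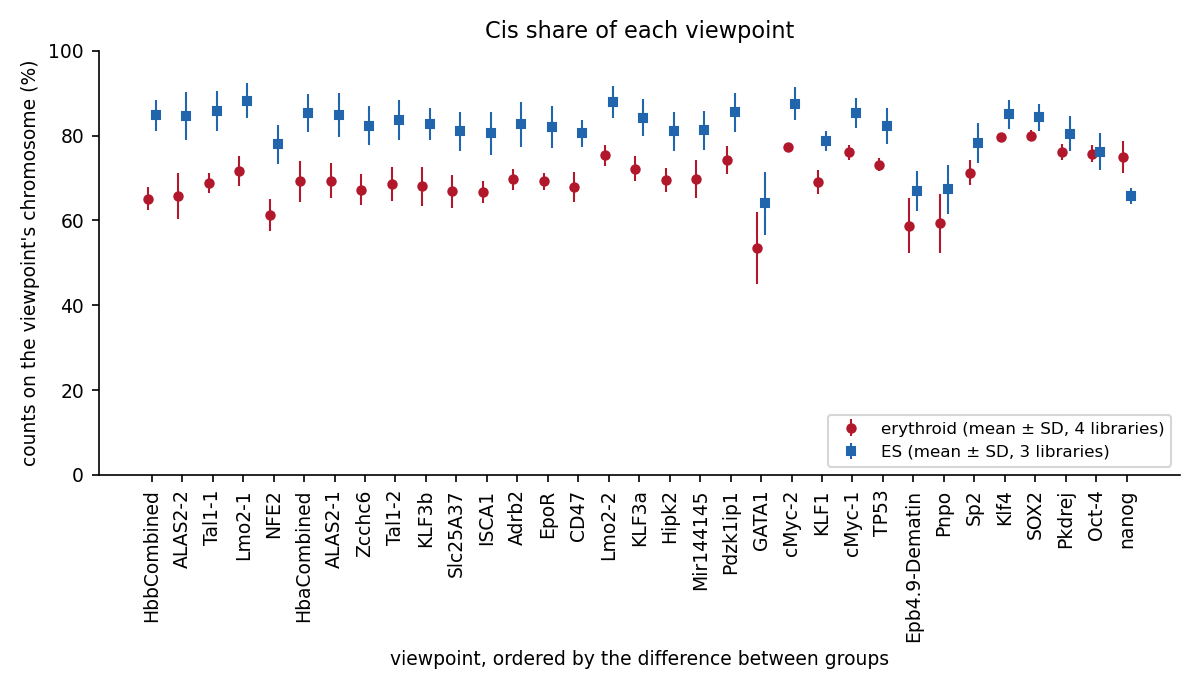
Percent of the counts of each of 33 viewpoints that lie on its own chromosome, as mean ± SD of 4 erythroid (red circles) and 3 ES (blue squares) libraries, ordered by the difference between the groups. Erythroid means lie below ES means except at Nanog, with 74.9% against 65.7%.

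Within 1 Mb of the promoters, contacts in erythroid cells were placed nearer by the median over viewpoints. Shares by distance are percent of the counts that lay 5 kb to 1 Mb from the viewpoint. Counts nearer than 5 kb, farther than 1 Mb or on other chromosomes were left out of them. The share of counts 20 to 100 kb away had a median over viewpoints of 38.6% ± 1.12 (SD, n = 4) in erythroid and 31.2% ± 0.684 (n = 3) in ES libraries (exact permutation p = 0.0286), and 19 viewpoints were higher and 6 lower in erythroid cells past the adjusted threshold. The share 100 to 500 kb away was 27.2% ± 1.25 against 32.4% ± 0.788 (exact permutation p = 0.0286), with 2 viewpoints higher and 16 lower, and that 500 to 1000 kb away was 8.69% ± 0.658 against 11.0% ± 0.339, with 5 higher and 18 lower. From 5 to 20 kb the values were 25.1% ± 2.82 and 23.4% ± 0.310, for which the medians gave an exact permutation p of 0.4, although 10 viewpoints were higher and 3 lower past the adjusted threshold.

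Nanog and Gata1 were the viewpoints whose share 100 to 500 kb away was higher in erythroid cells past the adjusted threshold. Of the counts 5 kb to 1 Mb from Nanog, 36.3% ± 0.697 lay 20 to 100 kb away in erythroid and 50.5% ± 0.355 in ES libraries. The Nanog share from 100 to 500 kb in erythroid libraries was 8.29 percentage points above the 23.9% ± 0.479 of ES libraries. Gata1 had 34.1% ± 1.26 against 23.4% ± 2.23 from 100 to 500 kb. Sox2 showed the common direction, with 31.8% ± 1.86 against 45.8% ± 0.325. Of the 132 tests over viewpoints and distances, 79 passed (smallest adjusted exact p = 0.0477). All 79 had the smallest possible exact p, 0.0286, and passed only because so many tests reached it. The shares of a viewpoint add up to its whole, and Alas2, Tal1 and Myc each entered more than once. The tests are thus not independent.

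Single and double capture were compared at alpha-globin, on a library that the labels give as the same sample. Double capture gave 310339 counts and single capture 10814, a ratio of 28.7, and 26346 against 5911 fragments with a count, a ratio of 4.46. Each fragment with a count held 11.8 counts on average with double and 1.83 with single capture. The number of reads sequenced was not taken into account, so these ratios do not measure enrichment by the second capture. The share of counts on chromosome 11 was 73.0% with single capture (Wilson 95% interval 72.1 to 73.8) and 72.5% with double capture (72.4 to 72.7), a difference not detectable at this depth. The upstream enhancer region held 14971 normalised counts with single and 14331 with double capture. Over the 197 bins of 5 kb within 500 kb that held a count in either library, the values correlated with Pearson's r of 0.998 and Spearman's rho of 0.871, a correlation across bins, which are not independent replicates. Single capture had no count in 25 of these bins. There was 1 library of each kind, so no test was made.

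The double capture sets of alpha-globin differed in strain, in ter119 selection and in captured genes, so they were compared as sets. Of 198 bins, 1 was lower in the ter119 set by edgeR's test and 0 were higher, with 33 at an unadjusted p under 0.05. With TMM factors 1 was lower, 0 were higher and 13 had an unadjusted p under 0.05. The share of counts on chromosome 11 was 62.8% and 64.7% in the ter119 and 72.5% and 69.2% in the unselected libraries. Part of the 33 can thus be a general shift on the scale of the viewpoint total. On that scale the lower bin, HbaCombined_32365001, lay 171 kb downstream, with 16.5 and 24.2 normalised counts in the ter119 libraries and 79.3 and 64.7 in the unselected ones (log2 fold change -1.83, edgeR adjusted p = 0.0106). Leaving out either ter119 library or the first unselected library gave 0 calls, and leaving out the second unselected library gave 35. Each of these fits left 1 library in a set, which was assumed to vary like the other set, so they do not show how stable the call is. The upstream enhancer region held 14678 and 14602 normalised counts in the ter119 and 14331 and 14267 in the unselected libraries.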

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

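The comparison of peaks on other chromosomes with a second table of the same promoter was chosen only after the peaks were seen.

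In 5 of 76 groups of erythroid values, a single library lay far from the others, where chance alone gives about 1 in 20, or 3.8. The Klf4 window held 903 normalised counts in library C2 and 690 to 703 in the other 3. Bin SOX2_34660001 held 69.4 in C2 and 33.7 to 39.1 in the others. Library F2 held 123 at nanog_122885001 against 89.2 to 93.9, 15.2 at HbaCombined_32460001 against 4.48 to 5.78, and 13.0 at HbaCombined_32500001 against 2.89 to 3.47. In each of these the erythroid libraries still lay apart from all 3 ES libraries.

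Counts on other chromosomes, outside the comparisons made, formed sharp peaks present in all 7 libraries. In 3 bins of 5 kb every library had at least 100 normalised counts. The lowest library held 200.5 for the erythropoietin receptor viewpoint EpoR on chromosome 1 (182385001 to 182390000), 131 for Tal1-2 on chromosome 1 (38825001 to 38830000) and 105 for Gata1 on chromosome 5 (135185001 to 135190000). At a limit of 50 there were 7 such bins in 5 viewpoints and none in the other 28. Of the 7, 0 differed between the groups past the threshold (exact permutation, smallest adjusted p = 0.300), or at an unadjusted p under 0.05. These bins were chosen for being present in every library, which leaves out peaks of only 1 cell type. The tests therefore do not show that peaks on other chromosomes are alike in both groups.

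Contact between chromosomes would spread over neighbouring bins, and a median of 0% of a peak's counts lay in the 4 bins beside it, with 3.12% at the EpoR peak, which argues against such contact for these peaks. Capture or alignment of an off-target sequence is consistent with the other test. The Tal1-2 peak held 280 normalised counts over all libraries, while Tal1-1, which shares its promoter zone, held 0 of 186655 counts there, which allows up to 1.61. The Myc peak on chromosome 13 likewise held 114 in the first Myc table and 0 of 215784 counts in the second, so 0% of either peak was found in the second table of its promoter. The other 5 peaks have no such second table, so an off-target sequence stays open for them.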

How the results depend on the processing

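Summing E1 and E2, scaling by counts within 1 Mb, thinning the libraries and crossing the replicate numbers were chosen only after the results were seen. All 36 named bins kept their direction and passed in each of the 751 pairs of bin and setting that gave a value. The settings with bins of 2 or 10 kb and with single fragments gave none for these bins. The bins were chosen for the largest changes in the same libraries, so this is not an independent check. The count of 3221 bins ranged from 2752 to 3255 with each library left out in turn, was 2995 with E1 and E2 summed, and moved beyond 1.5 times to 1726 with DESeq2 (957 higher, 769 lower) and to 1718 with a mean of at least 30 counts, where 2544 bins were tested. DESeq2 used size factors per viewpoint instead of the viewpoint total, and its median log2 fold change was -0.04. The nearer comparison is edgeR with TMM factors, which gave 2171 bins and a median of -0.07. The lower count under DESeq2 thus mixes a change of scale with a change of test. With cis totals the count was 2967, with limma 3142, and with either strain alone 3027 and 3140. Counted by fragments, 0 viewpoints passed for the share on the own chromosome, against 24. The difference between erythroid and other genes, 0.0354, had the opposite sign as a mean log2 fold change (-0.0615) and with counts within 1 Mb (-0.0589), and passed in none of the settings; the cause was not tested. The widened alpha-globin window had a log2 ratio of 0.57. The correlation of single and double capture was 0.993 in 2 kb and 0.999 in 10 kb bins. With each library left out, the exact tests of windows and shares cannot pass, so only values were compared, and the windows kept their direction.

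For the double capture sets, a replicate block gave 2 bins, and so did the block with crossed numbers, against 1; deviations of same-numbered libraries correlated at -0.114, so the numbers are not taken to pair the libraries. Leaving out each library gave 0 to 35 bins, with the lone library of a set assumed to vary like the other set. The plan for the panel held no replicate block. A paired analysis was also not possible, because the panel columns carry a strain letter and not the sample number. In simulated data with 200 changed bins the test found 20.9% of 1.5-fold changes, so small changes can be missed. The real data gave 3221 calls, so the share found there need not be the same.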

Other observations

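The tests by splits of the libraries, by the chromosome total, by distance and by depth were chosen only after the result was seen; the neighbour, fragment and strain tests were set before their results.

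Captured promoters that lie near each other gave a view of contacts with the surroundings of another captured promoter. The promoters themselves carry no counts in these data, so only fragments beside them, within 5 kb of the zone centre, were counted. The promoter of Isca1 held 1081 ± 102 normalised counts (SD, n = 4) in the 10 kb around the Zcchc6 promoter in erythroid and 554 ± 72.7 (n = 3) in ES libraries, 1.95-fold more, and the view from Zcchc6 gave 1406 ± 314 and 878 ± 86.3. Tal1-1 held 1416 ± 172 and 1100 ± 26.5 at its neighbour Pdzk1ip1, and Sp2 held 1066 ± 223 and 715 ± 26.5 at Pnpo, while the view from Pnpo gave 801 ± 128 and 697 ± 23.2. The first Lmo2 promoter went the other way, with 3203 ± 681 in erythroid and 3580 ± 525 in ES libraries at the second, and the view from the second gave 4299 ± 1108 and 3823 ± 392. None of the 9 such tests passed after adjustment (exact permutation, smallest adjusted p = 0.103). The view from Isca1 to Zcchc6 alone reached the smallest p these libraries allow (exact permutation p = 0.0286). A single test at that p cannot pass over 9 tests, so the adjusted values do not decide whether any 1 pair differed.

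In the libraries selected for ter119, the beta-globin locus control region held 10410 and 10607 normalised counts, within the range of the 4 panel erythroid libraries, 8223 to 11039. The alpha-globin region held 14678 and 14602, also within the panel's 11647 to 15596.

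A hypothesis was that neighbouring promoters change with their region rather than singly. Fold changes of bins seen from both promoters, at least 20 kb from each, correlated across bins with r of 0.749 for Tal1-1 and Pdzk1ip1 (97 bins), 0.635 for Isca1 and Zcchc6 (87 bins) and 0.764 for Pnpo and Sp2 (121 bins). None of 78, 68 and 102 shifts of the profile against each other gave an r as high, and the highest was 0.600. The lowest value, 0.635, is what a shared change of the region would give. Fold changes also fell with distance over all viewpoints, and neighbours lie at similar distances from each bin. Shifting breaks this common trend too, so the test cannot tell it from a shared change of the region. Bins are not independent, and both profiles come from the same libraries.

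Scaled by the viewpoint total, counts 5 to 500 kb from the promoters were lower in erythroid libraries, with a median log2 fold change of -0.81. The median was -0.22 with counts within 1 Mb as the scale and -0.07 with TMM factors. Only the real split, 1 of 35, gave as many as 3221 bins. The highest other split gave 1250, with all 3 ES libraries kept together. This argues against chance in the grouping but cannot exclude it, because a share of 35 splits cannot fall below 0.0286. A lower share on the own chromosome cannot be the whole cause, since the median log2 fold change was still -0.62 on that scale, nor can random ligation, which would leave far bins less affected, while bins 100 to 500 kb away lay below those 5 to 20 kb away by a difference of -0.59. The 2 deeper erythroid libraries differed from the 2 shallower ones by a median of 0.012. The totals were already the scale of this fit, so this median cannot decide on depth. Within each strain the deeper library had the lower median share on the own chromosome. These shares were 66.0% in C1 against 69.4% in C2, and 69.2% in F1 against 73.6% in F2. Depth stays open. A difference in fixation or digestion between spleen and culture and the cell type itself stay open and untested. Strain stays open too: the crossed and the C57Bl6 libraries alone gave medians of -0.88 and -0.86, but both differ in strain from the ES cells.

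The 12 bins with the largest rises could come from single fragments with a strain variant. Without the fragment that rose most, their median log2 ratio was 1.598, against 1.67 with it, and all 12 still separated the groups, which argues against this as the cause; variants that act over a whole bin were not tested.

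Within the erythroid libraries, the C57Bl6 pair against the crossed pair gave 0 bins of 3849 by edgeR's test, also with TMM factors, and 240 at an unadjusted p under 0.05. The other 2 ways to pair these libraries gave 252 and 108, and 0 past the threshold. These 3 splits are too few for a share under 0.05, so a strain difference was not decided.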
